A study of Mus musculus with 17 samples.

How the data were processed

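The series holds 17 ChIP-seq and input libraries of mouse spermatogenic cells. Per the labels' protocols, cells from digested testes were passed through a 40 micron sieve and fixed in 0.3% formaldehyde for 30 min at 4 °C. Their chromatin was digested with micrococcal nuclease (MNase) before immunoprecipitation. BRG1 was precipitated from wild type CD1 cells at postnatal day 12 (P12) and postnatal day 18 (P18), with 2 ChIP and 2 input libraries at each age. H3K27ac and H2AK119ub1 were each precipitated at P12 from 2 Brg1WT and 2 Brg1cKO libraries, with 1 shared input. Samples were grouped by their titles, ages and genotypes in the labels.

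5 region lists were analysed. They were the BRG1 peaks at P12, the BRG1 peaks at P18, and the H3K27ac regions that the authors classed as common to both genotypes, gained in Brg1cKO or lost in Brg1cKO. The coordinates are in build mm9, and reads were processed with Bowtie or Bowtie2, SAMtools, Picard, deepTools 2.5.2 and MACS2, per the submitters' processing notes, which give no role or order for these tools. Each BRG1 list is named as merged and given for both replicates of an age, per the labels. How the replicates were merged is not given in the sources used here. The peak names inside the P12 list all carry the mark of 1 library or batch (P12B1), as do those inside the P18 list (P18B2), and they state a threshold of 0.05. H2AK119ub1 and the input libraries were not analysed here. Gene positions in mm9 were not used here, and the supplied gene table is on another assembly. Regions are therefore named by mm9 coordinates counted from 1. The planned shares of regions at promoters and the 14 fixed gene lists were left out.

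The strength of a BRG1 peak was the deposited −log10 q value, as the authors' peak caller wrote it. It was used to describe, rank or filter peaks within a list. It also entered the regression described below, and 1 alternative applied the same cut of at least 3 to both lists. The score deposited beside it was 10 times that value rounded down to a whole number, in 99.99% of P12 and 100% of P18 peaks, and was not used. A further pair of BRG1 columns held values of 6.36e+28 and above or large negative values, had no interpretable scale, and was not used. The score deposited by the authors for gained and lost regions was a large negative number for every region. A fixed number, 426560219, divided by the size of the score gave a whole number within 0.02 for 99.9% of gained and 100% of lost regions, where chance gives 4%. The median of that whole number was 211 for gained and 207 for lost regions. This is not the scale of a likelihood ratio, which was the unit foreseen before the data were examined. A high score means a large whole number, whose meaning is not known. It equalled the region width within 10 bp in 10.2% of gained and 9.43% of lost regions, and its rank correlation with width across regions, which are not independent, was 0.169 and 0.138. The score was used only to rank regions for the naming rule and for 1 alternative. The highest scoring 50% of gained and lost regions had median widths of 162.5 and 157 bp and are not shown to be more certain calls. The deposited score of common regions was used for no result.

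The numbers in the names of the regions run along the chromosomes with gaps, so more numbers were given than the lists hold. For each chromosome, numbers were counted up to the last name on it. The P12 list held 18630 peaks under numbers up to 45757, the P18 list 3020 under numbers up to 5991, the common list 170137 up to 426566, the gained list 983 up to 28717 and the lost list 785 up to 26656. Why the other numbers are missing is not given in the sources used here. Some regions repeat the name of another region of their list, 279 at P12, 9 at P18, 8485 among common, 2 among gained and 2 among lost regions. They were counted as regions of their own. Read depth per library is not known from region lists, so no value has an error from depth, and none has an error between replicates.

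Overlap meant at least 1 bp. Distances were gaps between region edges. Chance overlap was measured by shifting 1 list along each chromosome by a random amount and wrapping it at the ends, 1000 times with fixed seeds, which is called a shift permutation test here. Shifts were limited to 100 for the common class, to 200 for distances to common regions and to 20 for the profile. The smallest two-sided p these can give is 0.002 for 1000 shifts and 0.02 for 100. A further set of shifts of 20 to 200 kb kept the regional density of peaks. Classes were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the contrasts of a family. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Stratified odds ratios are Mantel-Haenszel estimates. Regions are not replicates, so each p-value describes an association between lists and does not test an age or a genotype. The chance that a P12 peak was found at P18 was modelled by logistic regression on autosomal peaks, from −log10 q, width and H3K27ac overlap, and applied to chromosome X. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

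The shift test was tested on simulated data of 983 regions. Of 100 lists placed at random against the P12 peaks, 2 gave a p below 0.05. This check used 100 shifts per list and the rule of within 1 kb. Its random positions do not share the regional clustering of real regions. When 10% of regions were planted on P12 peaks, the excess over shifts was 9.82 percentage points. The regression was tested on 18630 peaks with no X effect simulated, where the simulated number of X peaks differed from the expected 12.81 by −0.47 on average over 50 runs. The simulated data followed a form that the fitted model contains, so a small difference was built in. The larger share of X names kept in the P12 list was not simulated, so the test cannot speak to it.

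The comparisons, their tests and most alternatives were fixed before the data were examined. These alternatives were the highest scoring 50% of a list, as many P12 peaks as there are P18 peaks, other overlap rules, merging of regions within 1 kb, covered length in place of number, P18 in place of P12 peaks, and common regions matched on width. The regions to be named were also fixed then. They were the 5 strongest P12 peaks found at P18, the 5 strongest peaks at each age alone, and the 10 gained and 10 lost regions with the highest score. Alternatives added after the data had been seen are named as such in the closing section.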

Results

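BRG1 is the ATPase of the SWI/SNF chromatin remodelling complex, and acetylation of histone H3 at lysine 27 (H3K27ac) marks active promoters and enhancers. The study mapped BRG1 in spermatogenic cells of wild type mice at P12 and P18, and mapped H3K27ac at P12 in cells with BRG1 (Brg1WT) and in cells from which it was removed with Mvh-cre, a germ cell Cre (Brg1cKO). At P12 the first wave of spermatogenesis has entered meiosis, and at P18 the testis is rich in pachytene spermatocytes. The lists held 18630 BRG1 peaks covering 17.9 Mb at P12 and 3020 peaks covering 1.63 Mb at P18. For H3K27ac they held 170137 common regions covering 54.6 Mb, 983 gained regions covering 0.144 Mb and 785 lost regions covering 0.113 Mb. The labels give each list for both libraries of a group together, no value had replicate error, and read depth is not known from the lists.

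The first comparison asked how BRG1 occupancy differed between P12 and P18. The P12 list was 6.17 times as long as the P18 list and covered 10.97 times the length. Nearly every P18 peak lay at a P12 peak. Of the 3020 P18 peaks, 2955 (97.8%, 95% interval 97.3 to 98.3) overlapped a P12 peak, against a mean of 1.204% after circular shifts (shift permutation test, two-sided, p = 0.002, the smallest p the shifts can give). In the other direction, 2908 of the 18630 P12 peaks (15.6%, 15.1 to 16.1) overlapped a P18 peak, against 0.197% after shifts (shift permutation test, p = 0.002). BRG1 peaks were also wider at P12, with a median width of 780 bp (95% interval 768 to 791) against 429.5 bp (414 to 446) at P18.

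The ratio of the lists depended on the threshold. At a −log10 q of at least 3 in both lists, 12934 P12 peaks and 676 P18 peaks remained, a ratio of 19.1. Among the 3020 strongest P12 peaks, 49.9% overlapped a P18 peak, and these held 50.8% of the P18 peaks. When an overlap had to cover at least 50% of a peak's own length, 4.99% of P12 peaks counted as found at P18. A difference between the ages cannot be set against replicate spread, and a longer list can also come from deeper sequencing or a stronger precipitation.

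The strongest peaks found at both ages lay on H3K27ac. A common H3K27ac region was overlapped by 87.7% of all P12 peaks found at P18, and by all 5 of the strongest. The first of these 5, on chromosome 8 at 77517585 to 77518235, had a −log10 q of 18.2, the highest in the list. The next ones lay on chromosome 4 at 56959400 to 56960466 (17.2) and on chromosome 16 at 56716679 to 56717542 (17.0). The last 2 lay on chromosome 18 at 75178356 to 75179167 (16.2) and on chromosome 10 at 57909199 to 57910256 (16.1). Among the 5 strongest peaks at P12 alone, 3 overlapped a common H3K27ac region, as did 53.3% of all P12 peaks not found at P18. Sets of 5 are too few to compare. The strongest peak at P12 alone, on chromosome 15 at 66409143 to 66409758 (15.8), lay 2580 kb from the nearest P18 peak. The 4th, on chromosome 10 at 52137103 to 52138097 (14.7), lay 35.2 kb from one. The other peaks of this set were on chromosome 4 at 150431411 to 150432046, and on chromosome 18 at 34380399 to 34381308 and at 13099866 to 13100392.

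Peaks at P18 alone were few and seldom lay on H3K27ac. Of the 65, 16.9% (8.76 to 28.3) overlapped a common H3K27ac region, against 80.9% (79.4 to 82.3) of the P18 peaks that overlapped a P12 peak. Their median −log10 q of 2.298 was close to the 2.42 of those peaks, but they were narrower, with a median width of 254 bp against 434 bp. Width was not matched in this comparison. The interval for the 65 holds 12.2%, the mean for all P18 peaks after shifts of 20 to 200 kb. By definition they lie off P12 peaks, which often sit on H3K27ac. The 65 are therefore not shown to be a distinct class of BRG1 sites. The strongest was on chromosome 12 at 104136799 to 104137599, with a −log10 q of 4.14, and it was the only one of the top 5 to overlap a common H3K27ac region. The nearest P12 peak was 19.8 kb away. A pair of the other 4, on chromosome 10 at 41023307 to 41023978 and on chromosome 12 at 100158260 to 100158436, lay 0.257 and 0.219 kb from a P12 peak. The remaining ones lay on chromosome 11 at 53137813 to 53137991 and on chromosome 10 at 118568977 to 118569089.

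P12 peaks that were found at P18 were the stronger and wider ones and lay more often on H3K27ac. Their median −log10 q was 6.97, against 3.61 for the 15722 peaks not found at P18, and their median width was 1249.5 bp against 690 bp. A common H3K27ac region was overlapped by 87.7% (86.4 to 88.9) of the peaks found at P18 and by 53.3% (52.5 to 54.1) of the others, an odds ratio of 6.24 (5.56 to 7.02; Fisher's exact test, two-sided, p = 4.1e-299). With P12 peaks split by strength into 10 bins of 1863, the share found at P18 was 0.0537% (0.00136 to 0.299) in the weakest bin and 54.9% (52.6 to 57.1) in the strongest. The share on H3K27ac was 37.7% (35.5 to 40.0) and 87.9% (86.4 to 89.4) in the same bins. With peaks compared within these bins, the odds ratio for H3K27ac overlap was 2.69 (2.37 to 3.04). Peak width was not matched in this comparison, and a wider peak can more easily meet both a P18 peak and an H3K27ac region.

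**Figure D1:**
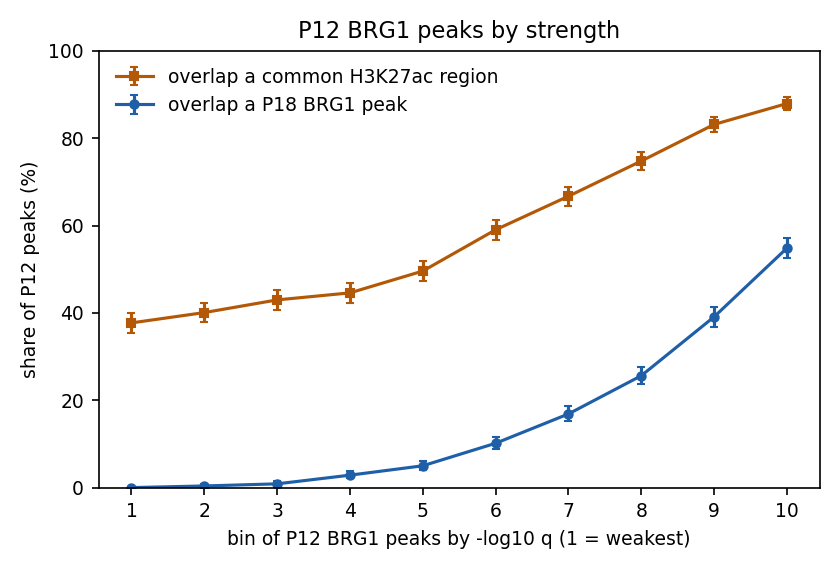
Share of P12 BRG1 peaks (%) that overlap a P18 BRG1 peak (circles) or a common H3K27ac region (squares), in 10 bins of −log10 q at P12 with 1863 peaks each and exact 95% binomial intervals as bars. The share found at P18 is 0.0537% in the weakest bin and 54.9% in the strongest, and the share on H3K27ac is 37.7% and 87.9%.

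BRG1 peaks coincided with H3K27ac at both ages. At P12, 58.7% (58.0 to 59.4) of peaks overlapped a common H3K27ac region, 7.13 times the mean of 8.23% after circular shifts. At P18 the share was 79.5% (78.1 to 81.0), 13.6 times the mean of 5.85%. In bins 9 and 10 of strength, P12 peaks had shares of 83.1% and 87.9%. The higher share of the shorter P18 list is therefore not shown to be a difference between the ages. Shifts of 20 to 200 kb, which keep peaks in their neighbourhood, gave means of 17.98% at P12 and 12.2% at P18. Each of these 4 shift permutation tests gave p = 0.002, the smallest possible. H3K27ac was measured at P12 alone, so the P18 share compares BRG1 at P18 with acetylation at P12. At the centres of P12 peaks found at P18, 55.7% lay in a common region, against 30.0% for the other P12 peaks and 2.36% after shifts. At 1 kb on the right of the centre, the shares were 15.4% and 9.62%.

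**Figure D2:**
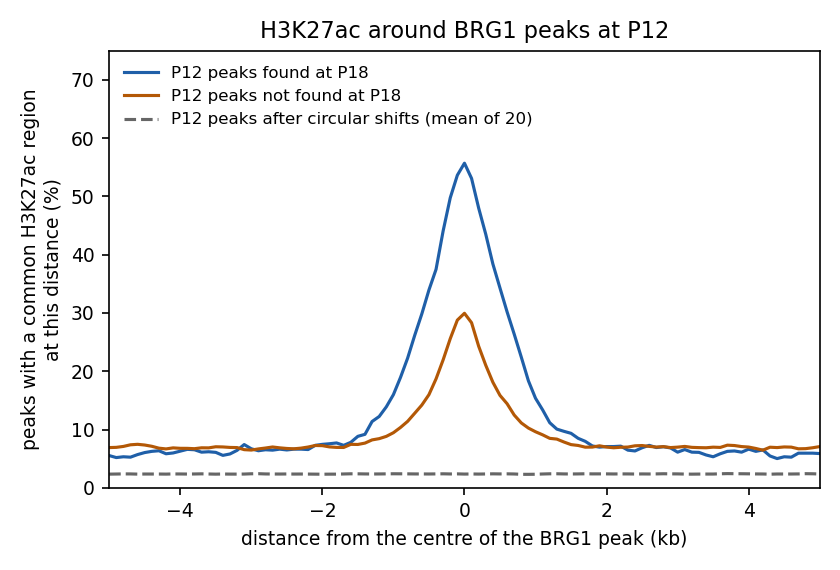
Percentage of P12 BRG1 peaks with a common H3K27ac region at each distance from the peak centre (kb), for peaks found at P18, peaks not found at P18, and the mean of 20 circular shifts of all P12 peaks. Both sets peak at the centre, at 55.7% and 30.0%, and the shifted peaks stay near 2.36%.

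The X chromosome was compared because it is silenced in pachytene spermatocytes. The P18 list held no peak on X, and the P12 list held 294. These made up 1.58% (1.40 to 1.77) of the P12 peaks. For P18, 0 of 3020 peaks allows a share of up to 0.0993% at a floor of 3 peaks, or 0.122% by the exact 95% interval. The odds ratio of P18 against P12 was 0, with an upper 95% bound of 0.0767. At the P12 share, 47.7 of the P18 peaks would have been on X. On autosomes, 2908 of 18336 P12 peaks (15.9%) were found at P18, and on X 0 of 294 (0 to 1.25%).

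X peaks at P12 were weak and were represented differently in the list. Their median −log10 q was 2.998, against 4.05 on autosomes. In the stronger 50% of the P12 list, X made up 0.784% of peaks, and of the 3020 strongest P12 peaks 2 (0.0662%, 0.00802 to 0.239) lay on X, so at equal list length the intervals of the ages overlap. The strongest X peak, at 160395946 to 160396501, had a −log10 q of 8.52 and was singled out after its value was seen. Of the numbers in the P12 peak names that fall on X, 84.5% were kept in the list, while each autosome kept between 36.8% and 44.7%. By those numbers, X held 0.761% of all numbered peaks.

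**Figure D3:**
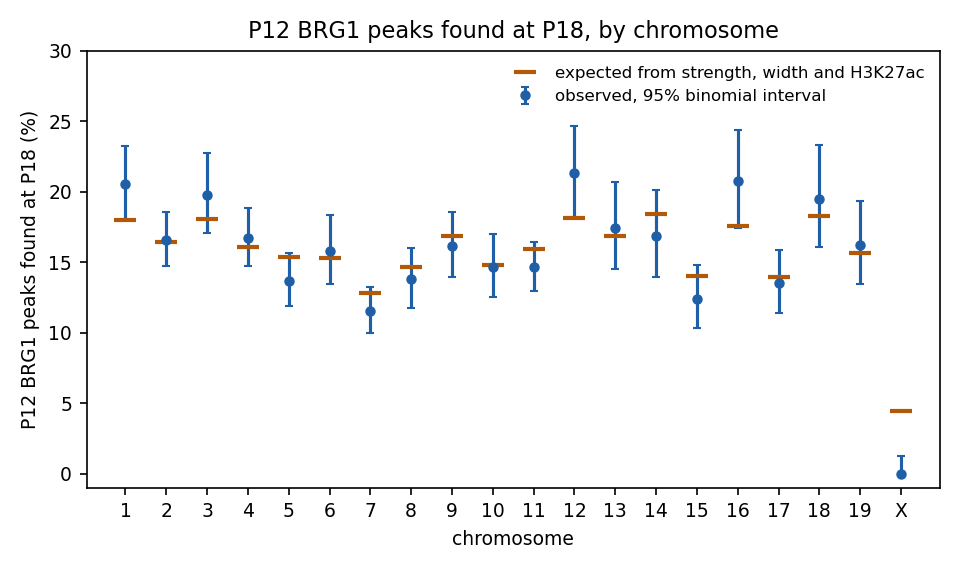
Percentage of P12 BRG1 peaks found at P18 on each chromosome, with exact 95% binomial intervals (circles and bars) and the percentage expected from a logistic model of strength, width and H3K27ac overlap fitted to the other autosomes (dashes). Autosomes lie between 0.888 and 1.18 times the expected number, and X is at 0 of 294 where the model expects 13.03, with no allowance for the larger share of X names kept in the P12 list.

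The next comparison asked how H3K27ac differed when BRG1 was removed. In the deposited lists, almost all H3K27ac regions were common to both genotypes. Common regions made up 99.0% of all regions and 99.5% of the covered length, gained regions 0.572% and lost regions 0.457% of all regions. These shares rest on lists that hold 37.9% of the numbers in the names of common regions, but 3.42% of those of gained and 2.94% of those of lost regions, for reasons not given in the sources used here. By the highest numbers in the names, gained and lost regions together would make up 11.5%. Gained regions outnumbered lost ones, 983 to 785, a ratio of 1.25 (1.14 to 1.38; exact binomial test, two-sided, p = 2.7e-06). By the highest numbers in the names, 28717 and 26656, the ratio was 1.08. The p describes the lists, since the calls of the authors carry no error between the 2 libraries per genotype. Gained and lost regions were narrow, with median widths of 150 and 145 bp against 271 bp for common regions, and 155 gained and 135 lost regions were narrower than 50 bp.

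Gained regions lay on X more often than common ones. X held 28 of 983 gained regions (2.85%, 1.90 to 4.09), 17 of 785 lost regions (2.17%, 1.27 to 3.44) and 2718 of 170099 common regions outside Y (1.60%, 1.54 to 1.66). The odds ratio of gained against common was 1.81 (1.19 to 2.63; Fisher's exact test, two-sided, adjusted p = 0.00913 over 2 contrasts). For lost against common it was 1.36 (0.789 to 2.20; Fisher's exact test, adjusted p = 0.198). Whether gained and lost regions differed from each other was not tested. Common regions were the only reference, and gained regions lie outside them by construction. Whether gained regions favour X against any other reference was not tested.

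Of the 10 named gained regions, 2 lay on X, at 101299185 to 101299263 and at 164375821 to 164375983. The one with the highest score was on chromosome 6 at 19972501 to 19974221. It was 1721 bp wide, the widest gained region, and lay 74.5 kb from the nearest common H3K27ac region and 1173 kb from the nearest P12 BRG1 peak. The second, also on chromosome 6, at 108514859 to 108514895, was the nearest of the 10 to a P12 peak, at 5.66 kb. None of the 10 overlapped a BRG1 peak of either age. The others lay on chromosome 1 at 130804078 to 130804245 and at 177666489 to 177666737, on chromosome 17 at 26777979 to 26778091, on chromosome 7 at 46760904 to 46761123, on chromosome 3 at 79757913 to 79758130 and on chromosome 10 at 12109797 to 12109933.

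Of the 10 named lost regions, 2 overlapped BRG1 peaks of both ages. They lay on chromosome 2 at 25995196 to 25996449 and on chromosome 3 at 75360501 to 75361713, and were 0.298 and 0.019 kb from a common H3K27ac region. They were 1254 and 1213 bp wide, against a median of 145 bp for lost regions. Of all 785 lost regions, 9 (1.15%) overlapped a P12 peak and 3 (0.382%) a P18 peak. The lost region with the highest score, on chromosome 14 at 8462485 to 8463692, lay 0.045 kb from a common region and 160 kb from a P12 peak. The third, on chromosome 17 at 58681001 to 58682173, lay 43.4 kb from a common region and 1262 kb from a P12 peak. The others were between 58 and 308 bp wide. They lay on chromosome 9 at 8029474 to 8029715, on chromosome 8 at 122650930 to 122651181, on X at 12633861 to 12634168, on chromosome 7 at 4532927 to 4533204, and on chromosome 19 at 26640883 to 26640940 and at 30845119 to 30845244.

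The last comparison asked whether H3K27ac regions that changed without BRG1 were sites of BRG1 binding. Direct overlap was rare in both changed classes. A P12 BRG1 peak was overlapped by 9 lost regions (1.15%, 0.526 to 2.17) and 13 gained regions (1.32%, 0.706 to 2.25), against 15335 common regions (9.01%, 8.88 to 9.15). The odds ratio was 0.117 (0.0533 to 0.223) for lost against common and 0.135 (0.0718 to 0.233) for gained against common (Fisher's exact tests, two-sided, adjusted p = 5.9e-21 and 3.4e-24 over 3 contrasts). Lost and gained regions did not differ detectably, with an odds ratio of 0.865 (0.325 to 2.20; Fisher's exact test, adjusted p = 0.831). The shares in lost and gained regions were close to those after circular shifts, 0.878% and 0.843% (shift permutation tests, p = 0.513 and 0.126). Against common regions of matched width, of which 4.89% and 4.82% overlapped a peak, the odds ratios were 0.226 for lost and 0.264 for gained (permutation p = 0.002 each, two-sided, the smallest the 1000 draws can give). Gained and lost regions lie outside common regions by construction, with 0 and 2 overlaps, which lowers their overlap with peaks that sit on H3K27ac.

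Lost regions lay within 1 kb of a BRG1 peak more often than gained ones. Within 1 kb of a P12 peak lay 51 lost regions (6.50%, 4.88 to 8.45) and 30 gained regions (3.05%, 2.07 to 4.33), an odds ratio of 2.21 (1.36 to 3.63; Fisher's exact test, two-sided, adjusted p = 8.0e-04). In shift permutation tests, circular shifts gave 2.39% for lost (p = 0.002) and 2.32% for gained regions (p = 0.142). The same test with shifts of 20 to 200 kb gave permutation means of 4.70% for lost (p = 0.022, adjusted p = 0.066 over 6 tests) and 3.24% for gained regions (p = 0.811). Within 10 kb these permutation means were 23.5% for lost regions, against 25.7% observed (p = 0.12, adjusted p = 0.24), and 17.5% for gained regions, against 20.1% observed (p = 0.018, adjusted p = 0.066). Neither class passed the adjusted test at either distance. Common regions lay within 1 kb of a peak more often than either, in 13.8% of cases (13.68 to 14.01).

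**Figure D4:**
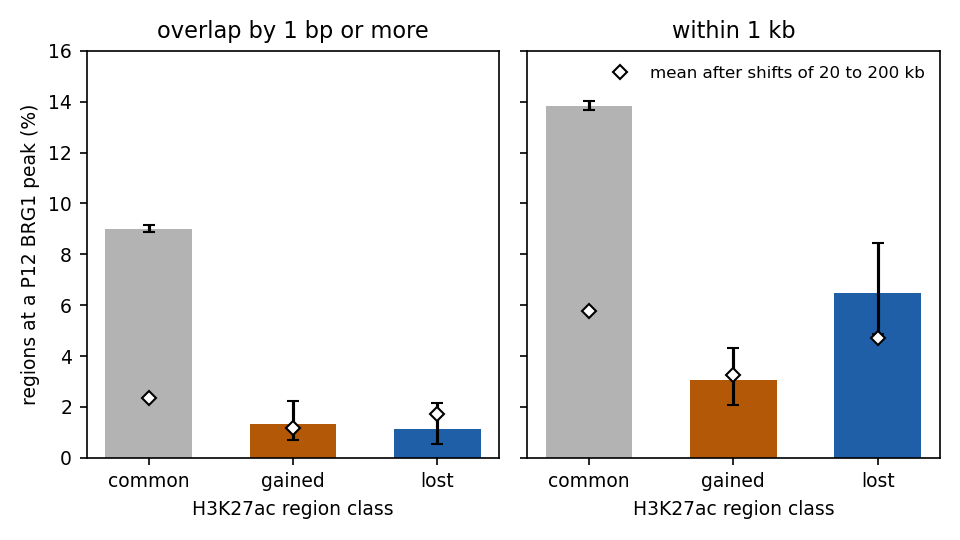
Percentage of common, gained and lost H3K27ac regions that overlap a P12 BRG1 peak (left) or lie within 1 kb of one (right), with exact 95% binomial intervals and the mean after shifts of 20 to 200 kb (diamonds). Direct overlap is 9.01% in common, 1.32% in gained and 1.15% in lost regions, and within 1 kb the shares are 13.8%, 3.05% and 6.50%.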

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

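No test in this part was chosen in advance. The common H3K27ac list held 38 regions on the Y chromosome among its 170137, which entered no comparison of X and autosomes. The gained and lost lists and both BRG1 lists held no Y region. These lists are far shorter than the common list, and their counts of 0 were not tested against its share on Y.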

How the results depend on the processing

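The alternatives added after the data had been seen were a −log10 q of at least 3, shifts of 20 to 200 kb, regions of at least 50 bp, distances of 5, 10 and 50 kb, P18 peaks within 1 kb, the numbers in the P12 names on X and in the names of gained and lost regions, and leaving out each chromosome. Of 59 values under alternatives, 43 kept their direction and side of the threshold, or stayed within their interval or 1.5 times their count. In 4 of these the outcome was fixed by construction and says nothing about stability: taking 50% of each list keeps a ratio of numbers (BRG1, gained to lost), and a P18 list with no X peak stays at 0 in its highest scoring 50% and by covered length. The other 39 were not fixed in this way. Those that compare lost or gained with common regions were still favoured in advance, since changed regions lie outside common ones by construction. For the overlap of the BRG1 lists, only direction and p were judged, not size. The share of P12 peaks found at P18 was 15.6% as deposited and 49.9% among the 3020 strongest. It was 4.99% when at least 50% of a peak's length had to be covered. The share of P18 peaks at a P12 peak was 97.8% as deposited and 50.8% against those 3020. Shifts of 20 to 200 kb change the permutation p and not these shares. The excess of gained over lost regions was 1.26 after merging within 1 kb and 1.08 by the highest numbers in the names, the alternatives that could have changed it. The overlap of both BRG1 lists with each other and the X odds ratios kept their direction and side of the threshold under every alternative run. So did the lower overlap of lost and of gained than of common regions, which for the reason above says little about stability.

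A −log10 q of at least 3 moved the ratio of peak numbers to 19.1, the median width at P12 to 955 bp and at P18 to 446.5 bp. The highest scoring 50% of each list had median widths of 1016 and 465.5 bp, and merging peaks within 1 kb gave 801 bp at P12. The X share at P12 was 0.784% in the highest scoring 50%, 1.27% by covered length, 0.0662% among as many peaks as at P18, and 0.761% by the numbers in the names. Stronger peaks were wider and fewer lay on X. The odds ratio of BRG1 occupancy, lost against gained, was 0.865 for overlap, with an interval of 0.325 to 2.20. The estimate lay above 1 at greater distances, at 2.21 within 1 kb, 1.39 within 5 kb, 1.37 within 10 kb and 1.41 within 50 kb. For P18 peaks within 1 kb it was 15.2 (12 lost and 1 gained region, interval 2.24 to 652). In the highest scoring 50% of the gained and lost lists it was 1.26 (Fisher's exact test, p = 0.788). Since the overlap interval holds values on both sides of 1, a reversal is not shown. Why the estimates differ was not tested. Causes of the difference within 1 kb are weighed in the last part. Leaving out each chromosome gave 1.96 to 2.74 within 1 kb.

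With no gained region in overlap, P18 peaks (3 lost) and as many P12 peaks as at P18 (1 lost) gave no ratio. No paired analysis was possible because each list is given for both replicates of a group together and holds no value per replicate, which also kept any replicate from being left out. Alternatives for promoters and gene lists were not run, since gene positions in mm9 were not used here. Read depth is unknown, so weak peaks and unequal list lengths limit every comparison of ages.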

Other observations

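The tests in this part were chosen after the result was seen, with these exceptions. The ratio of peak number and the X share of BRG1 peaks, at P18 and among the 3020 strongest P12 peaks, were chosen before. So were the contrasts of lost and gained regions by direct overlap and within 1 kb. The odds ratios matched on strength and on distance to common regions were also chosen before their result was seen. With gaps of up to 10 kb joined, 39.9% of P12 BRG1 peaks lay in 2649 clusters, a share that rises with list length. Among 3020 peaks it was 9.87% for P12 peaks drawn at random (100 draws, 7.91 to 11.7), 3.91% for the strongest P12 peaks and 6.52% for the P18 peaks, so the ages are not shown to differ. The largest cluster, on chromosome 10 at 80778960 to 80896946, held 28 P12 peaks and 63 common H3K27ac regions and no P18 peak. Another on chromosome 10, at 79741377 to 79875971, held 25 P12 peaks and 1 P18 peak. Of P12 peaks in clusters of 5 or more, 7.82% (6.60 to 9.19) were found at P18, against 16.4% (15.8 to 17.0) of the rest. Clustered peaks were weaker, with a median −log10 q of 3.24 against 4.14, and within 10 bins of strength the odds ratio was 0.989 (0.810 to 1.21).

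The longest common H3K27ac regions stood far above the median of 271 bp. They lay on chromosome 9 at 13167320 to 13217928 (50.6 kb), on chromosome 6 at 47596490 to 47636110 (39.6 kb) and on chromosome 5 at 26421182 to 26435731 (14.6 kb), and the next was 4.18 kb long. Lost regions lay within 10 kb of a common region in 81.5% of cases and gained regions in 71.8% (odds ratio 1.73, 1.37 to 2.19; Fisher's exact test, p = 1.8e-06).

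No P18 BRG1 peak lay on X. Dropout of weak X peaks from a shorter list is argued against as the whole cause, provided that X peaks are found as autosomal peaks are. Models of strength, width and H3K27ac fitted to autosomes expected 12.4 to 15.4 of the X peaks at P18, where 0 were found. With peaks taken as independent, these models gave 0 X peaks a chance of at most 1.1e-06. Scaled to the autosomal share of names kept, the lowest expectation was 5.84, with a chance of 0.0029 for 0 peaks. The models assume that X peaks are found at P18 as autosomal peaks are, though X names were kept at a different share at P12. Only 2 of the 3020 strongest P12 peaks lay on X, which points the other way. Those 3020 met 50.8% of the P18 peaks, so they stand in poorly for the P18 list. Matching on strength may overstate the expectation. X kept 84.5% of its names at P12 and no autosome above 44.7%, so X may have been treated differently when the lists were made. That share alone lowers the expectation to 5.84 and does not explain 0 peaks. How X was treated in the P18 list is not known, so different treatment there could still account for the gap. A change of the X chromosome between the ages, such as its silencing, stays open and cannot be told apart from this, since 0 X peaks follow from either.

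The P12 list was 6.17 times as long as the P18 list. Weaker signal or less depth at P18 may account for some of this. The share found at P18 was 54.9% in the strongest of 10 bins and 0.0537% in the weakest. A loss of BRG1 that left the strongest sites could give the same gradient, so it does not single out depth. H3K27ac at P12 went with being found at P18 at matched strength (odds ratio 2.69, 2.37 to 3.04). Peak width was not matched, and the association names no mechanism. A loss of BRG1 between the ages was not tested apart from depth.

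Lost H3K27ac regions lay within 1 kb of a P12 BRG1 peak more often than gained ones. Closeness to common regions is argued against as the whole cause, since the odds ratio matched on that distance was 1.93 (1.21 to 3.10). Regional density of BRG1 peaks differed between the classes and can account for part of the difference. Shifts of 20 to 200 kb, which keep it, gave means of 4.70% for lost and 3.24% for gained regions. Circular shifts gave 2.39% and 2.32%. Whether density accounts for all of it stays open. Against shifts of 20 to 200 kb the lost share gave a permutation p = 0.022, which became 0.066 when adjusted over 6 tests. That adjustment was adopted after the unadjusted value was seen. The p tests the lost share alone and not its difference from the gained share. Within 10 kb the gained share gave a permutation p = 0.018, and with P18 peaks the lost share gave 0.012 within 1 kb and 0.018 within 10 kb (gained 0.128 and 0.773), but over all 12 tests the lowest adjusted p was again 0.066. A fall of acetylation beside BRG1 sites is a hypothesis that direct overlap leaves open, since its odds ratio of 0.87 (0.325 to 2.20) reaches both ways.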
